A study of Homo sapiens with 2 samples.

How the data were processed

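Total RNA from NCI-H838 cells was sequenced 48 hours after transfection with a plasmid for LINC00472 or with the empty plasmid, 1 library per group, and groups were taken from the sample titles. The authors deposited read counts per gene, as whole numbers that were not normalized, and FPKM (fragments per kilobase of transcript, scaled to library size) in a table of both libraries and in a table per library. The deposited counts of all 27685 genes were identical between the tables. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 1.3.4b and the build hg19, without roles or order. Whether reads were counted directly or estimated from coverage, whether the library marked strand, and how ribosomal RNA was removed are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be separated. No coordinates are printed, because the annotation used here is for another build.

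The deposited counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), which were 1.11 for the LINC00472 library and 0.905 for the control. The main measure was the log2 ratio of LINC00472 over control with a prior count of 0.5 scaled to library size. Its interval was the exact conditional (Clopper-Pearson) 95% interval of the ratio of 2 counts. It covers counting error only, since reads are not independent molecules and cultures were not replicated. A gene met the size rule with a mean of at least 1 CPM, a log2 ratio of at least 1 or at most -1, and an interval excluding a ratio of 1. Where a library had a count of 0, the fold is a lower bound against a floor of 3 counts per library. The floor is a one-sided limit, so the interval allows a somewhat smaller fold. Counting error alone was simulated in 100 pairs of Poisson libraries with equal means. Shares of counts have exact Clopper-Pearson 95% intervals. With 21093055 and 54823706 counts these intervals are narrow for abundant genes, and genes near the minimum, such as MMP1 and CA9, have wide ones.

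Gene lists (32, including single genes of interest) were fixed before the data were examined, as were the size rule, the named genes and the alternatives unless stated otherwise. Each list with at least 5 members at the minimum was described by the percentile of its median log2 ratio among 10000 random lists of the same size. These were matched on mean expression in 20 bins and drawn from genes of all classes at the minimum. Named genes were the genes of interest, the 12 highest and 12 lowest by the interval bound nearest to equality among those meeting the rule at 5 CPM or more, and up to 4 members with the largest absolute ratio from each list standing apart or holding calls. Members named beyond that rule, such as MYL9, ROCK1, PCNA, POLA1, MKI67, AXIN2, RNF43, ITGA2, ITGB4, COL4A1, FN1, CDH1, CDH2, ZEB1, CXCL2, CCL20, RPL15, RPS16, ABCC3, NQO1, FTL, RMRP, RPPH1, MALAT1 and the neighbours of LINC00472, were chosen after their values were seen. Some genes that the rule names are not reported here.

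Gene types, transcript length, GC content and intron length came from GENCODE 29, matched by gene ID and transcript for 96.9% of genes at the minimum. Adjusted ratios are residuals of a linear model with splines (5 knots, degree 3) of log2 transcript length, GC content and log2 intron length, fitted in scikit-learn 1.9.0 over 13583 genes, with the median added back. The model took up 0.116 of the variance (R squared). Alternatives fixed beforehand were total-count scaling, DESeq2 1.42.0 size factors, upper quartile factors, a prior count of 5, FPKM with 0.5 added, the single-library tables, other expression minimums, and totals without the 100 most abundant genes. Alternatives added after seeing the data were the adjusted ratios, the control thinned to equal depth, protein-coding genes alone, random lists also matched on length, and long noncoding RNAs set against protein-coding genes in the same of 20 bins of expression.

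The procedure was tested on simulated data for this comparison, with 14054 genes at the minimum and 200 genes changed. The size rule recovered 100 of 100 genes changed 4-fold and 99 of 100 changed 3-fold, and called 2 of 13854 unchanged genes. Intervals held the true ratio for 95.3% of genes, and 4.0% of 300 unshifted lists fell outside the bounds. The simulated counts varied by counting error alone, without variation between cultures or libraries. These rates therefore do not show how the size rule, the intervals or the list bounds perform when cultures or libraries vary. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.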

Results

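RNA was sequenced from NCI-H838 cells, an established line of human lung adenocarcinoma, 48 hours after lipid-mediated transfection. One culture received a plasmid carrying LINC00472, a long intergenic noncoding RNA, and the other received the empty plasmid. The comparison asks which transcripts differ when this noncoding RNA is supplied in excess. Each group held 1 library, so no difference below has a replicate check, no p-value is given, and intervals cover counting error only. The LINC00472 library held 21093055 gene counts over 18238 genes with a count. The control library held 54823706 over 18910 genes, out of 27685 genes listed in both. Genes are called higher or lower where they met a rule of size, namely a mean level of at least 1 CPM (counts scaled to the size of the library), at least a 2-fold ratio and a 95% counting interval that excluded equality.

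LINC00472 (NCBI gene ID 79940) was higher in the library labelled as overexpressing it. It had 5655 counts there against 2563 in the control, or 25.3 against 4.74 in the deposited FPKM. The ratio of TMM-scaled counts was 4.69-fold (log2 2.23, 95% counting interval 2.16 to 2.30). Other long noncoding RNAs were higher as well. Of 45 with a mean level within 4-fold of that of LINC00472, 6 had a ratio as high or higher, and their median log2 ratio was 0.75. Of 774 at the expression minimum, 101 were as high or higher. The control library thus held reads assigned to LINC00472 without the insert. The genes near LINC00472 in the genome, SMAP1 (log2 ratio -0.77), OGFRL1 (-0.43) and FAM135A (0.55), did not meet the rule. With ratios adjusted for transcript properties, 1 of them was lower.

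Of 14012 genes at the expression minimum, 2288 were higher and 3341 were lower in the LINC00472 library. Counting error alone gave a mean of 2.02 and at most 6 such genes in 100 simulated pairs. The balance of the calls depended on the scaling. TMM placed 40.7% of them on the higher side, total-count scaling placed 57.9% there (3154 higher, 2297 lower), and upper quartile factors 63.9% (3530 higher, 1993 lower). The median log2 ratio of all genes was -0.19 with TMM, 0.11 with total counts and 0.21 with upper quartile factors, and each ratio below is read against the TMM value. The higher calls lay at low levels more often than the lower ones, and 1347 higher and 3052 lower calls remained at a minimum of 5 CPM.

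**Figure D1:**
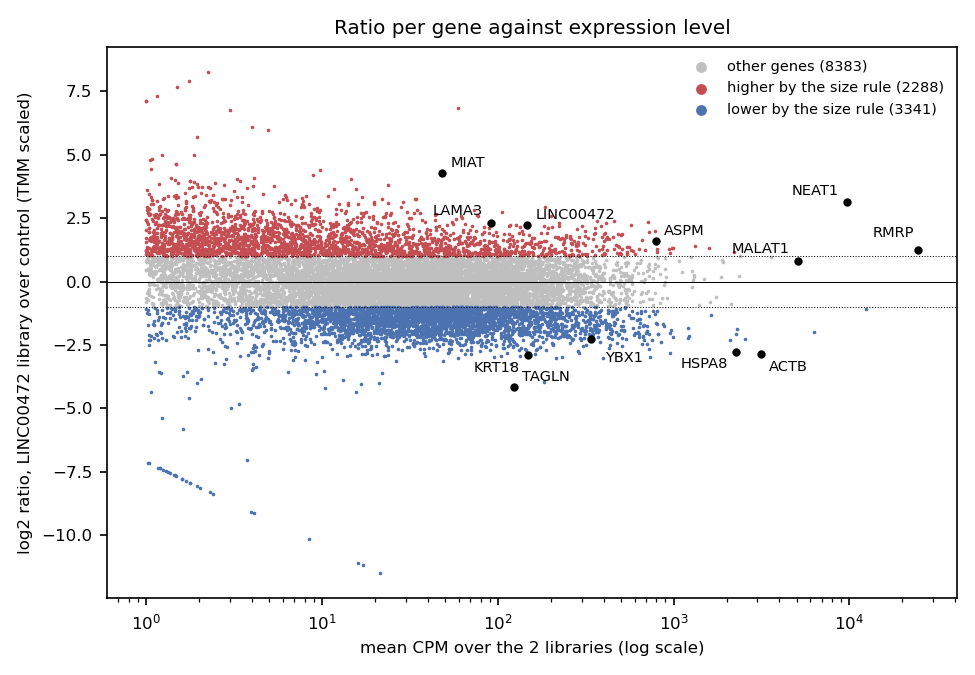
Log2 ratio of the LINC00472 library over the control (vertical axis, TMM scaled) against mean CPM (horizontal axis, log scale) for the 14012 genes at the minimum; dotted lines mark a 2-fold ratio, black points are named genes, and the lowest blue points are genes with a count of 0 in the LINC00472 library, drawn with the prior count. Red genes (2288) were higher and blue genes (3341) lower by the size rule, with NEAT1 at 3.16 and TAGLN at -4.18.

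The genes with the highest bounds on the higher side were mostly noncoding or poorly resolved loci. MIAT, a nuclear long noncoding RNA, was 19.3-fold higher (2153 against 237 counts), and NEAT1, the scaffold RNA of nuclear paraspeckles, was 8.92-fold higher (405102 against 96676 counts), with a log2 ratio of 3.16 that fell to 1.80 when adjusted for transcript length, GC content and intron length. LINC01876 was 9.56-fold higher, and the noncoding loci LOC101928978 and LOC339874 were 12.5-fold and 13.6-fold higher. Among protein-coding genes, ADAM20 was higher with a log2 ratio of 3.81, and BLID and MTHFD2L, a mitochondrial folate enzyme, were 12.7-fold and 9.61-fold higher. RALGAPA1P1 was 114-fold, RGPD8 21.1-fold, HLA-L 18.3-fold and the readthrough locus MSH5-SAPCD1 16.6-fold higher. These 4 share sequence with related genes or overlap other genes, so their counts are uncertain.

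On the lower side, MUC4, a membrane mucin, had 0 counts in the LINC00472 library and 2125 in the control, a ratio at least 333-fold lower against a floor of 3 counts per library (the counting interval ends nearer to equality, at log2 -8.08). KCNJ12, a potassium channel gene, had 0 against 836 counts (at least 131-fold lower). TIGD1 had 0 against 1606 (at least 252-fold) and the readthrough locus C15orf38-AP3S2 0 against 1698 (at least 266-fold). TIMP3, an inhibitor of metalloproteinases, was 18.2-fold lower, TAGLN, an actin-binding protein, 18.1-fold, TNNC1, a troponin, 15.9-fold and THY1 12.1-fold. HIST3H2A was 16.6-fold, OVCA2 14.7-fold and the readthrough locus ANKHD1-EIF4EBP3 20.2-fold lower. RNR1, a mitochondrial ribosomal RNA, was 15.5-fold lower (517 against 17116 counts). Readthrough, transposon-derived and multi-copy loci such as C15orf38-AP3S2, TIGD1, KCNJ12 and the histone gene are uncertain for the same reason as above.

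Noncoding classes and protein-coding genes differed between the libraries. Of 775 long noncoding RNAs, 385 were higher and 41 lower (median log2 ratio 0.99). Of 153 small nucleolar and Cajal body RNAs, 104 were higher and 0 lower (median 1.39), and of 253 pseudogenes 133 were higher and 17 lower (1.05). Of 29 microRNA loci, 18 were higher and 3 lower (1.60). Of 12357 protein-coding genes, 1396 were higher and 3242 lower (-0.31). Long noncoding RNAs took 7.76% of counts in the LINC00472 library (exact 95% interval 7.75 to 7.77) and 2.55% in the control (2.545 to 2.554). NEAT1 alone took 1.92% against 0.176%, and MALAT1, another nuclear RNA, 0.720% against 0.336%. RMRP, the RNA of the ribonuclease MRP, took 3.83% against 1.32%, while RPPH1, the RNA of ribonuclease P, went the other way with 0.874% against 1.52%. Mitochondrial ribosomal RNA took 0.0121% against 0.0952%.

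Short messenger RNAs were lower than long ones. Among protein-coding genes the median log2 ratio ran from -1.30 in the decile of shortest transcripts (median 900 nt) to 0.24 in the decile of longest ones (median 7926 nt). Across these genes, which are not independent replicates, Spearman's correlation of the ratio was 0.35 with transcript length, 0.33 with total intron length and -0.20 with GC content. Median transcript lengths and percentiles of ratios adjusted for these properties are therefore given beside some of the gene groups below.

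**Figure D2:**
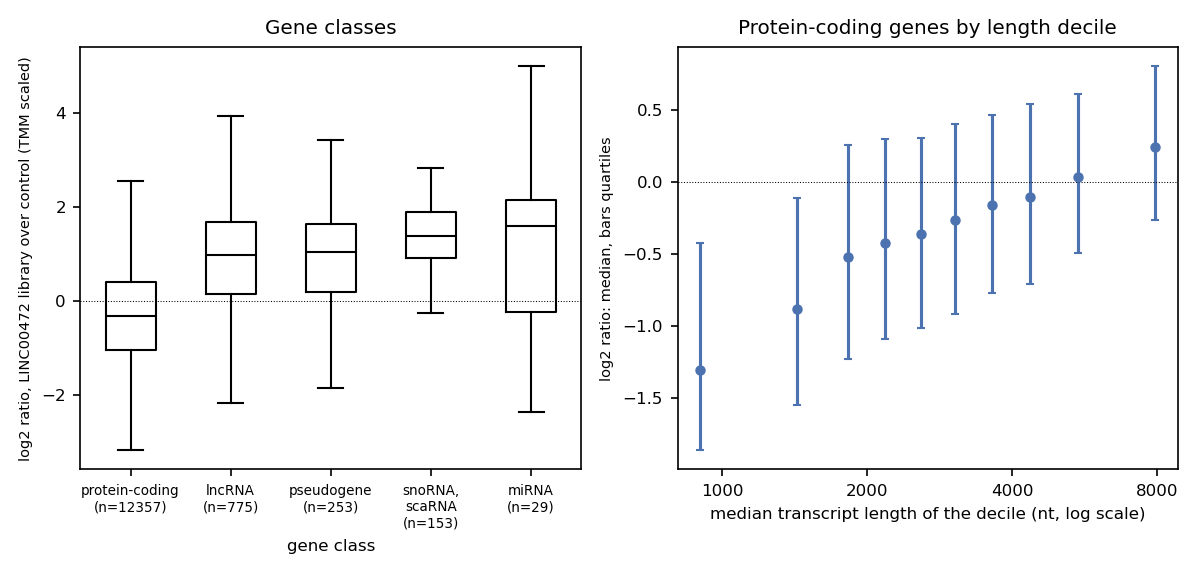
Left, log2 ratio of the LINC00472 library over the control by gene class (boxes are quartiles with the median, whiskers reach 1.5 times the box, outliers not drawn); right, median and quartiles of the ratio in 10 deciles of transcript length (log scale) over protein-coding genes. The small nucleolar and Cajal body RNAs have a median of 1.39 and protein-coding genes of -0.31, and the decile medians run from -1.30 to 0.24.

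Of 27 gene lists with at least 5 measured members, 11 stood apart low and 1 high against random lists matched on expression. By chance 1.35 are expected outside the bounds. Random lists were drawn from all genes at the minimum, including noncoding classes, whose medians lay above that of protein-coding genes (-0.31). The fixed lists hold mainly protein-coding genes, so part of their low standing may reflect gene class, also for adjusted and length-matched percentiles. Random lists of protein-coding genes alone were not drawn. Standing apart means a median outside the central 95% of 10000 random lists, as a description of these libraries. Adjusted medians of the actin (-1.50), S phase (-1.45), ribosomal protein (-1.46), heat shock (-1.69) and NRF2 (-1.55) lists lay near -1.59. That was the adjusted median of 60 messenger RNAs for cytosolic proteins, a list drawn up once the data were known. Histone (-2.38) and squamous (-4.11) lists lay lower, and the other 4 low lists higher. A change particular to the functions of those near -1.59 was not separated from one of cytosolic messenger RNAs.

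**Figure D3:**
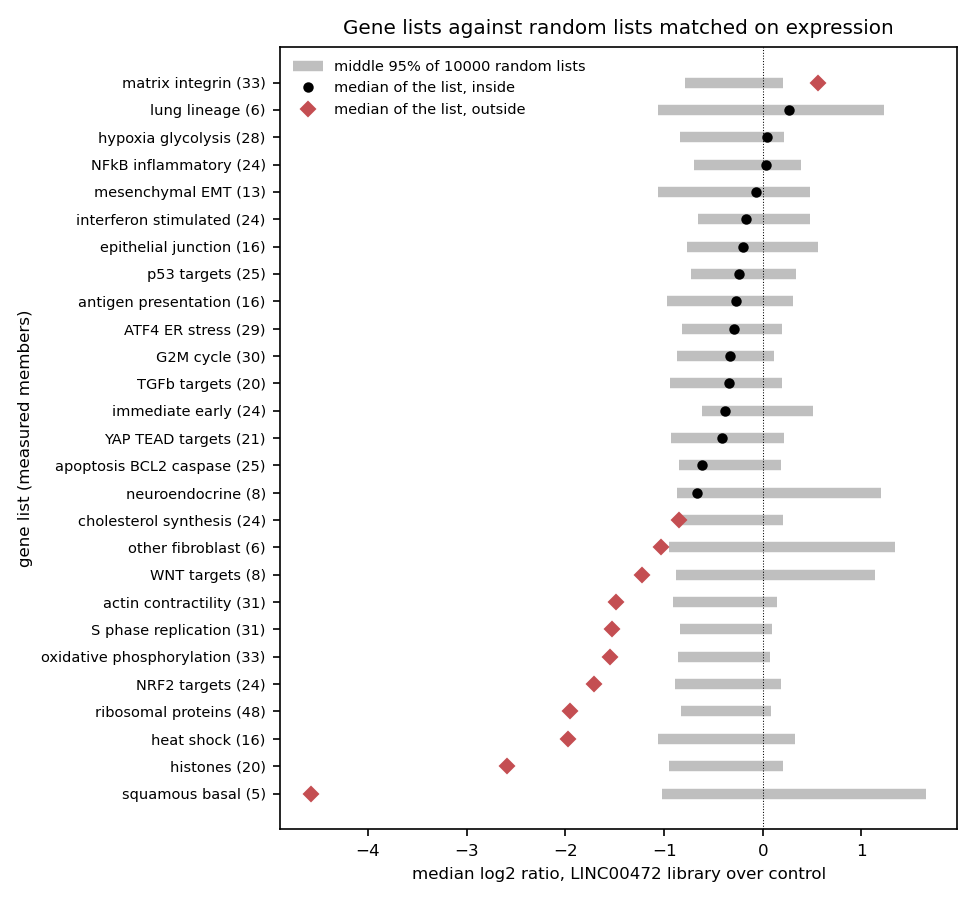
Median log2 ratio of each gene list (points; number of measured members in brackets) and the middle 95% of 10000 random lists of the same size matched on expression (grey bars). Matrix and integrin genes (0.56) lie above their bar, and 11 lists from cholesterol synthesis (-0.85) to squamous and basal genes (-4.58) lie below theirs.

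Genes of the actin cytoskeleton and contractility were lower as a group. Of 31 measured, 20 were lower and 0 higher, with a median of -1.49 (percentile 0.01; adjusted 0.0; median transcript 2493 nt). The cytoplasmic actins ACTB and ACTG1 were 7.30-fold and 7.89-fold lower, the calponins CNN1 and CNN2 8.72-fold and 8.12-fold lower, and the myosin light chain MYL9 6.54-fold lower. ROCK1, a kinase that drives contractility, had a log2 ratio of 0.07. Matrix and integrin genes stood apart on the opposite side. Of 33 measured, 14 were higher and 5 lower, with a median of 0.56 (percentile 99.99; adjusted 100.0; 4603 nt). The higher members included the laminin chain LAMA3 (4.92-fold), tenascin TNC (3.76-fold), integrins ITGA2 (2.88-fold) and ITGB4 (2.80-fold), the collagen COL4A1 (2.43-fold) and, from 56 against 22 counts, the collagenase MMP1 (5.27-fold). ITGA2 (log2 ratio 0.92) and COL4A1 (0.97) were among those that fell short of 2-fold with adjusted ratios. The metalloproteinase inhibitor TIMP3 was lower. With upper quartile factors 16 matrix genes were higher and 2 lower, and with adjusted ratios 8 were higher and 4 lower.

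Genes of mesenchymal cells did not stand apart. Of 13 measured, 2 were higher and 3 lower (percentile 68.7; adjusted 62.3; 3206 nt). Vimentin VIM was 3.32-fold, S100A4 5.01-fold and TAGLN 18.1-fold lower, whereas fibronectin FN1 was 2.65-fold and the lysyl oxidase LOX 2.80-fold higher. N-cadherin CDH2 (log2 ratio -0.06) and the repressor ZEB1 (0.12) did not meet the rule. Of 16 epithelial junction genes, 4 were lower and 0 higher (percentile 38.1), and the list reached percentile 0.75 when genes down to 0.1 CPM were included. The lower members included the simple keratins KRT18 (7.46-fold) and KRT8 (3.96-fold) and plakophilin PKP3 (3.90-fold), and E-cadherin CDH1 had a log2 ratio of 0.47.

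Target genes of pathways linked to adhesion were mixed. Of 21 YAP and TEAD targets, 7 were lower and 1 higher (percentile 39.9), with ANKRD1 6.56-fold lower and CTGF at a log2 ratio of -1.32 (-0.93 with upper quartile factors), and upper quartile factors left 2 lower and 2 higher. Of 20 TGF-beta targets, 5 were lower and 2 higher (percentile 52.2), with ID2 4.19-fold and ID3 4.01-fold lower. Of 8 WNT targets, 5 were lower and 0 higher, and the list stood apart (median -1.22, percentile 0.37; adjusted 0.82; 3312 nt). Its lower members included the cyclin CCND1 (3.68-fold) and MYC (4.14-fold), while AXIN2 (log2 ratio 0.95) and RNF43 (0.33) went the other way without meeting the rule. With upper quartile factors 3 were lower and 1 higher.

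**Figure D4:**
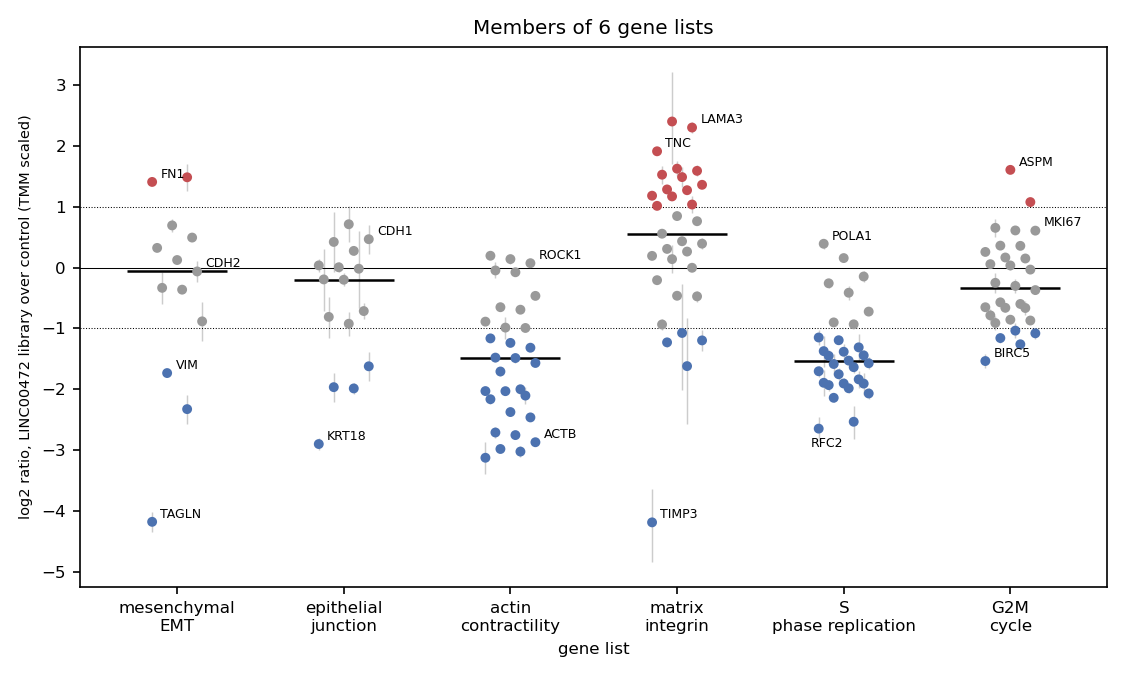
Log2 ratio of the LINC00472 library over the control for each measured member of 6 gene lists, with 95% counting intervals (grey bars), list medians (black lines) and 2-fold ratios (dotted lines); red members were higher, blue lower and grey neither by the size rule. Actin genes have a median of -1.49 and S phase genes of -1.53, while matrix and integrin genes have 0.56.

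DNA replication genes were lower as a group, whereas mitotic genes did not stand apart. Of 31 replication and S phase genes, 23 were lower and 0 higher (median -1.53, percentile 0.0; adjusted 0.0; 2724 nt). The clamp loader subunit RFC2 was 6.26-fold, GINS2 5.78-fold, the helicase subunit MCM2 4.40-fold, the licensing factor CDC6 4.19-fold and the sliding clamp PCNA 3.95-fold lower, while the polymerase POLA1 had a log2 ratio of 0.39. Of 20 replication-dependent histone genes, 19 were lower and 0 higher (median -2.60, percentile 0.0; adjusted 0.0; 537 nt). HIST1H2BO was 7.91-fold lower, and histone genes took 0.0990% of counts against 0.419% in the control. Histone genes are near-identical copies, so single members are uncertain. Of 30 genes of G2 and M phases, 5 were lower and 2 higher (percentile 54.2; adjusted 93.6; 2857 nt). BIRC5 was 2.90-fold and the cyclin CCNA2 2.39-fold lower, the spindle gene ASPM was 3.04-fold higher (adjusted log2 ratio 1.01), and MKI67 had a log2 ratio of 0.61. CCNA2 fell short of 2-fold with total counts (log2 ratio -0.97) and upper quartile factors (-0.87). The balance of the G2 and M calls turned with the scaling, to 1 lower and 2 higher with total counts and 1 lower and 3 higher with upper quartile factors, and adjusted ratios gave 3 lower and 1 higher.

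Genes of translation and respiration were lower. Of 48 ribosomal protein genes, 46 were lower and 0 higher (median -1.95, percentile 0.0; adjusted 0.0; 860 nt), with RPS2 6.32-fold and RPS15 6.08-fold lower. RPL15 (log2 ratio -0.97) and RPS16 (-0.93) fell short of the rule. Ribosomal protein genes took 0.937% of counts (exact 95% interval 0.933 to 0.941) against 2.93% (2.928 to 2.937), and many have pseudogene copies that can share reads. Of 33 nuclear-encoded respiratory chain genes, 25 were lower and 0 higher (median -1.55, percentile 0.0; adjusted 0.06; 1120 nt), including NDUFB10 (4.27-fold) and UQCRC1 (3.87-fold). Against random lists also matched on transcript length, the respiratory chain list reached a percentile of 3.13 and no longer stood apart. Of 13 protein genes of the mitochondrial genome fixed beforehand, 0 were matched by name in the deposited data, so they could not be described.

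Heat shock and antioxidant genes were lower. Of 16 heat shock genes, 13 were lower and 0 higher (median -1.97, percentile 0.0; adjusted 0.0; 2432 nt). The chaperone HSPA8 was 6.80-fold, the small heat shock proteins HSPB1 and CRYAB 7.34-fold and 7.45-fold, and DNAJA1 5.59-fold lower. Of 24 targets of the antioxidant factor NRF2, 16 were lower and 2 higher (median -1.71, percentile 0.0; adjusted 0.0; 2043 nt). The heme oxygenase HMOX1 was 12.4-fold, TALDO1 5.56-fold, the quinone reductase NQO1 4.91-fold and the ferritin light chain FTL 4.84-fold lower, while the transporter ABCC3 was 2.66-fold higher. With upper quartile factors 14 NRF2 targets were lower and 4 higher. Of 24 cholesterol synthesis genes, 8 were lower and 0 higher (median -0.85, percentile 1.84), with ACAT2 5.38-fold lower. That list did not stand apart with adjusted ratios (15.8), with FPKM (2.58), at 5 CPM (3.09) or against length-matched lists (4.65), and 4 members were lower and 2 higher with upper quartile factors. Of 29 ATF4 and endoplasmic reticulum stress genes, 9 were lower and 2 higher (percentile 51.2), and 4 were lower and 4 higher with upper quartile factors.

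Inflammatory and hypoxia genes held members in both directions. Of 24 NF-kB targets and inflammatory mediators, 5 were higher and 3 lower (percentile 75.6; adjusted 99.2; 1914 nt). The chemokines CXCL8 (4.72-fold), CXCL2 (2.95-fold) and CCL20 (2.86-fold) were higher, and CXCL10 (3.46-fold) and RELB (3.49-fold) lower. Of 28 hypoxia and glycolysis genes, 3 were higher and 8 lower (percentile 88.8). The carbonic anhydrase CA9 was 14.3-fold higher from 85 against 12 counts and the enolase ENO2 3.65-fold higher, while the glycolytic enzymes GAPDH and PGAM1 were 4.98-fold and 4.88-fold lower. The hypoxia list stood apart on the high side with FPKM (97.9), adjusted ratios (99.0) and length-matched lists (99.4). With upper quartile factors 9 NF-kB genes were higher and 2 lower, and the balance of the hypoxia genes turned to 7 higher and 6 lower.

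Of 24 interferon-stimulated genes, 6 were lower and 1 higher (percentile 37.1), with ISG15 4.49-fold lower, and the balance turned to 3 lower and 4 higher with upper quartile factors. Of 16 antigen presentation genes, 4 were lower and 0 higher (percentile 55.5), and with adjusted ratios 2 were lower and 1 higher. Of 25 p53 targets, 9 were lower and 1 higher (percentile 43.0), with the cell cycle inhibitor CDKN1A 3.55-fold lower and the ubiquitin ligase subunit FBXW7 3.20-fold higher. Of 25 BCL2 family and caspase genes, 10 were lower and 0 higher (percentile 13.2), and of 24 immediate early genes 6 were lower and 2 higher (percentile 13.4). Upper quartile factors gave 5 lower and 2 higher p53 targets and 5 lower and 1 higher apoptosis genes. They turned the balance of the immediate early genes to 2 lower and 4 higher.

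Among single genes of interest, YBX1, an RNA-binding protein named with LINC00472 in earlier work, was 4.84-fold lower (log2 -2.28, interval -2.33 to -2.22; 2703 against 27859 counts). MYC was 4.14-fold lower (log2 -2.05, interval -2.39 to -1.74; 90 against 796 counts). The adjusted log2 ratio of YBX1 was -1.98, and 49 of 60 other messenger RNAs for cytosolic proteins, from a list drawn up once the data were known, were lower. The following genes did not reach a 2-fold ratio. Log2 ratios were 0.87 for EGFR, 0.63 for FOXO1, 0.33 for EP300, 0.11 for NFE2L2 and 0.11 for STK11. They were -0.48 for KEAP1, -0.64 for PDCD4, -0.80 for YBX3 and -0.83 for KLLN. EGFR reached 1.16 with total counts and 1.26 with upper quartile factors, and FOXO1 1.02 with the latter. KLLN reached -1.11 with adjusted ratios.

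Markers of other lineages were also measured. All 5 squamous and basal genes at the minimum were lower (median -4.58, percentile 0.0). KRT5 and KRT6A had 0 counts in the LINC00472 library and 395 and 407 in the control, ratios at least 61.9-fold and 63.8-fold lower, and KRT17 was 4.62-fold lower. Keratin genes include close copies, so these counts are uncertain. Of 6 fibroblast markers, 3 were lower and 1 higher (median -1.03, percentile 1.74), with FAP 4.41-fold higher and THY1 12.1-fold lower, and the list lost its standing with total counts (5.41), upper quartile factors (5.26) and equal depth (6.39). Of 8 neuroendocrine genes, 3 were lower and 2 higher (percentile 5.55), with CHGA at 0 against 177 counts and SCG2 5.74-fold higher. Of 6 lung lineage genes, 1 was lower and 2 higher (percentile 65.9). With upper quartile factors 3 neuroendocrine genes were lower and 3 higher, and 0 lung lineage genes were lower and 3 higher. Of the leukocyte markers, CD14 was 2.48-fold higher and CD68 (log2 ratio -0.70) met no call, and the 2 endothelial, red cell and liver markers at the minimum met none. With upper quartile factors 1 endothelial, red cell or liver marker was higher.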

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

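Ratios adjusted for transcript properties, the thinned control, protein-coding genes alone and length-matched lists were chosen after seeing the data. No paired analysis was possible because each group held 1 library. Counts of genes by the size rule stayed within 1.5 times of 2288 higher and 3341 lower, with these exceptions. Upper quartile factors gave 3530 higher and 1993 lower, of which 2288 and 1993 were shared. No filter on low counts gave 3657 higher, a minimum of 5 CPM 1347 and protein-coding genes 1396, because other genes were tested. Within that range, FPKM gave 2369 higher and 2402 lower, and adjusted ratios 1751 and 3239 (1494 and 2634 shared). The LINC00472 log2 ratio was 2.52 with total counts, 2.62 with upper quartile factors, 2.30 with FPKM and 2.34 adjusted, outside its counting interval; the scaling factors account for the former pair, and the cause of the others was not tested. Lists standing apart high numbered 2 with FPKM, 3 with adjusted ratios and 2 with length matching, against 1; low lists numbered 7 at 5 CPM, against 11, where fewer lists could be tested. Without the 100 most abundant genes the totals were 17246393 counts for the LINC00472 library and 46579398 for the control, and ribosomal protein shares 0.876% and 2.55%. Of 143 other named genes, no called gene changed sign in any setting; ratios left their counting interval for 98 with total counts, 111 with upper quartile factors, 118 with FPKM, 85 adjusted and 27 with the thinned control. No list call changed side. Depth limits genes near 1 CPM, where a count of 0 in the LINC00472 library allows up to 3 counts.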

Other observations

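The tests of transcript length alone and of depth, the weighing of a response of the cells, and the rank of LINC00472 among long noncoding RNAs were chosen after the result was seen (for the rank, a near-identical value over all long noncoding RNAs), and the ratios adjusted for transcript properties and the thinned control were added after seeing the data. The test of depth took the place of a count of calls with the thinned control, which thinning could hardly change. The gap between long noncoding and protein-coding medians with the thinned control was also tried and set aside for the same reason. The reading of length-matched lists beside adjusted ones was also added after the results were seen. Besides the 32 fixed lists, of which 27 had enough measured members, 5 lists of other tissues and 2 lists by place of protein synthesis were written after the patterns they test were seen, from genes whose own values had not been looked at.

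Messenger RNAs of 2 lists, drawn up by where their proteins are made, differed. Of 60 genes for cytosolic proteins, such as proteasome subunits, chaperonin subunits and tubulins, 49 were lower and 0 higher in the LINC00472 library (median log2 ratio -1.82). Of 60 genes for secreted, lysosomal and membrane proteins, 6 were lower and 6 higher (median -0.26). Their median transcripts were 1946 nt and 3042 nt, and after adjustment for transcript properties the medians were -1.59 (percentile 0.0 of random lists) and -0.43 (percentile 90.6). Only the cytosolic list thus stood apart, and place of synthesis was not separated from the function of the genes.

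The widest pattern was that noncoding RNAs were higher while ribosomal protein, histone and short abundant messenger RNAs were lower in the LINC00472 library. GC content and depth are each argued against as the whole cause. Of the gap between long noncoding and protein-coding medians, 97.6% was left after adjustment for GC content. Against protein-coding genes of the same level, through which depth acts, 67.8% was left (bootstrap interval over genes 61.8 to 76.8). Level may account for the rest. With the control thinned to equal depth 99.8% was left, though thinning could hardly change this gap. Transcript length as the whole cause is argued against for long noncoding RNAs and pseudogenes, by their annotated lengths. Their median transcripts (1716 nt and 1891 nt) were shorter than that of protein-coding genes (2805.5 nt). Yet their median log2 ratios were higher (0.99 and 1.05 against -0.31), and protein-coding genes of 1636 to 1999 nt had -0.52. Small nucleolar RNAs, short as annotated, lay 1.70 log2 units above protein-coding genes. Reads of overlapping genes could not be separated, so these small nucleolar counts, and part of those of other noncoding classes, may come from longer RNAs. Adjustment for length, GC content and intron length together left ribosomal protein, histone, S phase, heat shock, actin and NRF2 lists at percentile 0.0 and matrix and integrin genes at 100.0, while the respiratory chain, at 0.06, is left open because it lay inside the bounds (3.13) against length-matched lists. Still open is a hypothesis in 2 related forms. First, the LINC00472 library may hold more unspliced or nuclear RNA. The partial Spearman correlation of the ratio with intron length was 0.18 (interval 0.159 to 0.194, across genes). That with transcript length was larger, at 0.29 (0.2728 to 0.3055), so transcript length as a part of the cause also stays open. Second, the LINC00472 library may hold less cytosolic RNA with nuclear and reticulum-bound RNA kept. The difference of adjusted medians was 1.16 (bootstrap interval over genes 0.938 to 1.52), although RPPH1, also nuclear, was lower. How ribosomal RNA was removed is not known here, and a difference in library preparation was not tested. A response of the cells to LINC00472 cannot be told apart from such a difference in the RNA recovered, because there was 1 library per group.

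The higher level of LINC00472 itself is the second pattern. Among long noncoding RNAs of like level, 86.7% had a lower ratio than LINC00472, which is inside the central 95% of that class. The ratio may therefore reflect the shift of the class as well as the plasmid, and the counts cannot separate plasmid-borne from endogenous transcripts. No further test of the plasmid's share was run.

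The third pattern is that some squamous keratins had counts in the control library and 0 in the LINC00472 library, though KRT16 (3), KRT15 (14) and KRT17 (966) had counts there, among 27 genes at 0 in the LINC00472 library with at least 100 control counts, against 6 the other way at a minimum of the same level (47 counts), a cut chosen after seeing the data. KRT5 (395), KRT6A (407), KRT13 (159), MPO (239) and CHGA (177) were such genes, with their control counts in brackets, but those with the most counts were MUC4 (2125) and the readthrough, transposon-derived and multi-copy loci C15orf38-AP3S2 (1698), TIGD1 (1606) and KCNJ12 (836). A candidate explanation is reads of other tissue in the control library, and of 30 unseen squamous mucosa genes the 24 with at least 10 counts had a median log2 ratio of -2.43, with 11 at 0 in the LINC00472 library, such as CLCA4 (0 against 39), GBP6 (0 against 32) and CRNN (0 against 12). With zeros set at their bound, a condition added after the result was seen, the median was -1.23. TGM1 (log2 ratio -2.52), CSTB (-2.34) and FABP5 (-2.24) were lower but had counts in both libraries. Genes such as RHCG (0.51), ECM1 (0.55), KRT15 (0.56) and SERPINB4 (14 against 0) went the other way. The list thus leaves a squamous source and a difference of the cells open. The median over 7 muscle genes was -0.77, inside the quartiles of protein-coding genes (-1.04 to 0.40), and the other lists gave -2.96 over 4 myeloid genes, 0.33 over 2 pancreatic and -5.08 over 1 intestinal gene (-1.36 for the myeloid and -1.91 for the intestinal list with zeros at their bound), too few to weigh.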
